A study of Mus musculus with 6 samples.

How the data were processed

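Liver biopsies of 6 C57BL/6 mice, 4 labelled lean-chow and 2 labelled DIO-NASH, were measured by single-cell RNA sequencing, and each mouse gave 1 library. The submitters' processing notes name bcl2fastq 2.20.0.422, Cell Ranger 1.1.0, Seurat 3.1.1 and the genome build GRCm38. The annotation release and the authors' cell filters were not given in the sources used here. The deposited values are log-normalised expression, the natural log of 1 plus 10000 times the UMI count over the total of the cell. UMI counts were recovered by undoing the log and dividing the values of each cell by its smallest value above 0, and 100% of the values were whole multiples within a tolerance of 0.01. The files listed a union of 16000 genes, of which 11094 were in every file. No cell had under 201 genes or over 50.0% mitochondrial UMIs, and the lowest UMI count was 298, 291, 512 and 350 in lean mice 1 to 4 and 500 in both DIO-NASH mice.

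The design, the gene lists, the markers, the rule for named genes and a set of other settings to try were fixed before the data were examined. The design assumed count tables. Since the deposited unit was a log scale, its stated fallback was used, limma 3.58.1 (trend) on log2 of the mean CPM over the cells of a class plus a pseudocount of 1, in place of a test on counts. A mean over cells gives each cell equal weight, and the pseudocount draws the fold changes of low genes toward 0. Adjusted p values are Benjamini-Hochberg values over the genes tested in a class, and they measure the spread between mice, with 4 and 2 mice.

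Several choices were made after results had been seen. The planned cell filter (at least 200 genes, at least 500 UMIs and at most 25% mitochondrial UMIs) left 88, 86, 64 and 19 lean and 1370 and 2501 DIO-NASH cells and no class with enough cells, so all 6888 cells except 16 called doublets were used. The doublet calls covered 0.232% of the cells, under the 0.5% at which the method is taken to have worked, so doublets were in effect not removed. The gene filter was replaced: the first (at least 10 UMIs in at least 2 mice) called 4, 0 and 98 genes in the endothelial-like, phagocyte and T and NK-like classes, and the filter used (a mean CPM of at least 3 UMIs in the shallowest summed library) called 12, 1 and 10. Comparisons with lean mice 3 and 4 or lean mice 1 and 2 alone, CPM over nuclear-encoded UMIs, voom weights on the summed UMIs, the pseudocounts of 10 and 50, genes listed in every file and the leaving out of the top 5% of doublet scores were added after the data were seen.

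Cells of all mice were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 1). A cluster took the name of the class whose markers scored highest among 165 marker genes, with at least 3 markers detected and no more markers of another class among its top 10 genes. After its genes were read, 1 cluster with markers of different cells was left unnamed by hand. Mononuclear phagocyte-like cells joined the Kupffer-like and the monocyte or macrophage-like clusters. A class was tested for single genes where at least 30 cells were present in at least 3 lean and both DIO-NASH mice, which held for 3 classes. The UMIs of the summed libraries were 81157, 78848, 315502 and 96539 (lean) and 31904 and 810250 (DIO-NASH) in endothelial-like cells, 83176, 81830, 111894, 68885, 944898 and 2478563 in phagocytes, and 21330, 17822, 97652, 63005, 872600 and 405155 in T and NK-like cells. A count of 3 UMIs, the limit that a count of 0 allows, was 3.70 to 94.0 CPM in endothelial-like cells and 3.44 to 168 CPM in T and NK-like cells. Intervals and such limits cover counting error only.

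Shares of 12 classes were compared by limma on log2 of the cells plus 0.5 over the total plus 1, with adjustment over the classes, beside exact two-sided permutation tests over all 15 splits. Gene lists with at least 3 measured members were tested by camera with a preset correlation of 0.01 on log2 CPM, without the weights that the design had planned, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance one way. Adjusted p values of lists cover all 47 tests. Named genes were those past an adjusted p of 0.05 with a mean of at least 50 CPM in the higher group and groups that did not overlap, the 8 largest each way, and the 3 lowest-p members of each list (2 for lists with under 8 measured members). Some genes that this rule took are not reported here. Other genes of the lists named in the text were chosen after their values were seen. Gene positions are from GENCODE M21 (GRCm38).

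The procedure was tested on simulated data with 200 changed genes in 10 draws per class. The genes fitted were 1286 to 1411 in endothelial-like cells, 2256 to 2420 in phagocytes and 475 to 530 in T and NK-like cells. The changed part thus differed, and the shares called cannot be compared between classes. All genes had 1 common spread between mice and no clusters were simulated, so the shares do not measure the power in these data. At a log2 fold change of 2, the median share called was 68.1% in endothelial-like cells, 31.1% in phagocytes and 70.8% in T and NK-like cells, and at 1 it was 14.0%, 1.68% and 21.2%. The share of false calls ran from 4.72 to 24.8% in endothelial-like cells, 0 to 12.1% in phagocytes and 0.833 to 20.3% in T and NK-like cells, so it can exceed 5%. With no changed genes, 6 of 10 endothelial draws made a call, with at most 3 genes. Other software was python 3.11.15, R 4.3.3, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.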

Results

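Liver biopsies of 6 C57BL/6 mice were profiled by 10x Genomics 3′ single-cell RNA sequencing, with 1 library per mouse. The labels place 4 mice in a lean-chow group with a healthy diagnosis and 2 mice in a DIO-NASH group. The comparison asks how the liver cells of the DIO-NASH mice differ from those of the lean mice. The libraries of lean mice 1 to 4 held 448, 475, 590 and 423 cells, and those of DIO-NASH mice 1 and 2 held 1953 and 2999. Their total unique molecular identifiers (UMIs, each marking 1 captured transcript) were 218162, 228891, 934818 and 387548 in the lean mice and 3004771 and 5716329 in the DIO-NASH mice. The median UMI count per cell was 453, 427, 1341.5 and 810 in the lean mice and 1155 and 1344 in the DIO-NASH mice, so lean mice 1 and 2 were the shallowest. Mitochondrial transcripts made up a median of 27.9%, 26.6%, 39.4% and 42.9% of the UMIs of a lean cell and 18.6% and 10.995% of those of a DIO-NASH cell. The number of cells was 484 ± 73.8 (SD, n = 4) in lean and 2476 ± 740 (SD, n = 2) in DIO-NASH mice. The median mitochondrial share was 34.2% ± 8.17 against 14.8% ± 5.37 (exact two-sided permutation p = 0.133 for both, the smallest that 15 splits of 4 and 2 mice can give). The median UMI count was 758 ± 427 (SD, n = 4) against 1249.5 ± 134 (SD, n = 2; exact two-sided permutation p = 0.267).

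Clustering of 6872 cells gave 19 clusters, of which 18 were named from marker genes. They were joined into 12 classes for shares, where the mononuclear phagocyte-like class includes the Kupffer-like class. Endothelial-like, mononuclear phagocyte-like and T and NK-like cells had enough cells per mouse for tests of single genes. The remaining cluster held 112 cells led by basophil genes (Mcpt8, Cpa3) together with patrolling monocyte genes (Ear2) and stayed unnamed, with 2, 0, 10 and 3 cells in the lean mice and 38 and 59 in the DIO-NASH mice.

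Neutrophil-like cells, marked by S100a8, S100a9 and Retnlg, took a larger share of the cells kept in the DIO-NASH libraries. They made up 4.71% ± 2.55 (SD, n = 2) of the cells there, 127 and 87 cells, against 0.321% ± 0.367 (SD, n = 4) in the lean mice, with 1, 1, 5 and 0 cells. The limma fit of log2 shares gave a log2 ratio of 3.73 (SE 1.07, 95% confidence interval 1.46 to 6.01, adjusted p = 0.0346), and both DIO-NASH mice lay above all 4 lean mice. In lean mouse 4 the count was 0 of 421 cells, which allows a share of up to 0.713%. Hepatocyte-like cells made up 2.94% ± 3.38 (SD, n = 4) of the lean and 0.170% ± 0.194 (SD, n = 2) of the DIO-NASH cells, with 2, 12, 46 and 4 lean cells against 6 and 1 DIO-NASH cells. The log2 ratio was -3.86 (SE 1.21, 95% confidence interval -6.43 to -1.29, limma adjusted p = 0.0346). The exact two-sided permutation test gave p = 0.133 for both classes, which is the smallest p that the 15 splits allow. All shares are of the cells captured and kept, so they do not measure the composition of the liver.

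Shares of 3 further classes did not overlap between the groups and did not pass the limma threshold. Endothelial-like cells made up 37.0% ± 3.20 (SD, n = 4) of lean cells and 1.59% and 22.4% of the cells of the DIO-NASH mice, with exact binomial 95% intervals of 1.08 to 2.25% and 20.9 to 24.0% (log2 ratio -2.62, limma adjusted p = 0.100). Plasmacytoid dendritic-like cells, the main producers of type I interferon, made up 4.69% ± 2.52 against 0.788% ± 0.263 (log2 ratio -2.40, limma adjusted p = 0.100). Kupffer-like cells, the resident macrophages of the liver, made up 5.06% ± 2.39 against 10.7% ± 0.0603 (log2 ratio 1.16, limma adjusted p = 0.443). B-like cells made up 6.84% ± 9.84 against 20.02% ± 13.3 (adjusted p = 0.136), and T and NK-like cells 11.3% ± 4.83 against 20.3% ± 12.3 (adjusted p = 0.606). B-like shares of lean mice 1 to 4 were 0.671%, 0.423%, 21.3% and 4.99%. Their log2 ratio was 2.77, and 3.79 without lean mouse 3 (limma adjusted p = 0.0287). It was 4.79 against lean mice 1 and 2 alone (0.0293) and 0.76 against lean mice 3 and 4 alone (0.832). Of 296 cholangiocyte-like cells in the DIO-NASH mice, 289 came from DIO-NASH mouse 2, and the class share was 1.24% against 5.01% (limma adjusted p = 0.606). The other classes had adjusted p values of 0.443 (erythroid), 0.748 (mesenchymal), 0.842 (mononuclear phagocyte) and 0.926 (dendritic).

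The shares depended on how cells were kept and named. The files kept cells from 298, 291, 512 and 350 UMIs upward in the lean mice and from 500 in both DIO-NASH mice. Thus cells under 500 UMIs are present in 3 of the lean libraries only, while the neutrophil-like cluster had a median of 703 UMIs. The neutrophil log2 ratio was 1.41 (limma adjusted p = 0.161) with a common minimum of 500 UMIs, 200 genes and at most 25% mitochondrial UMIs, and 1.17 (adjusted p = 0.382) with each cell named by its own marker score. That minimum left 1, 0, 0 and 0 neutrophil-like cells among 87, 86, 64 and 19 lean cells, against 52 and 63 in the DIO-NASH mice, so the added 0.5 cells set most of the lean shares and the ratio of 1.41 is no measure of a smaller difference. The marker score named 19, 18, 7 and 3 of 447, 473, 588 and 421 lean cells neutrophil-like, and 130 and 95 of 1951 and 2992 DIO-NASH cells. With it the shares of the groups overlapped. Leaving out lean mouse 1, 2 or 4 or DIO-NASH mouse 1 or 2 gave neutrophil adjusted p values of 0.0578, 0.145, 0.102, 0.127 and 0.0790. Leaving out lean mouse 2 or 4 or DIO-NASH mouse 1 or 2 gave hepatocyte adjusted p values of 0.174, 0.102, 0.127 and 0.272. The hepatocyte log2 ratio without DIO-NASH mouse 2 was -2.49, and its adjusted p was 0.0572 with called doublets kept. The endothelial log2 ratio was -0.72 without DIO-NASH mouse 1 (adjusted p = 0.478) and -4.52 without DIO-NASH mouse 2, where it passed (0.00808). The Kupffer log2 ratio turned to -0.69 with the common minimum and was 0.26 with the marker score per cell and 0.36 at clustering resolution 2. With the common minimum, B-like cells (3.54) and plasmacytoid dendritic-like cells (-2.54) passed (adjusted p = 0.0167 for both), from 0, 1, 1 and 0 and 5, 3, 2 and 1 lean cells. As a share of immune cells, plasmacytoid dendritic-like cells passed as well (-2.90, adjusted p = 0.0136), and dendritic-like cells passed at resolution 2 (3.30, adjusted p = 0.0268). There a cluster of 203 cells led by Cst3, Naaa and Irf8, with 18, 18, 11 and 48 lean cells, was left unnamed, which left 2, 1, 2 and 0 lean dendritic-like cells in place of 20, 19, 13 and 48.

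**Figure D1:**
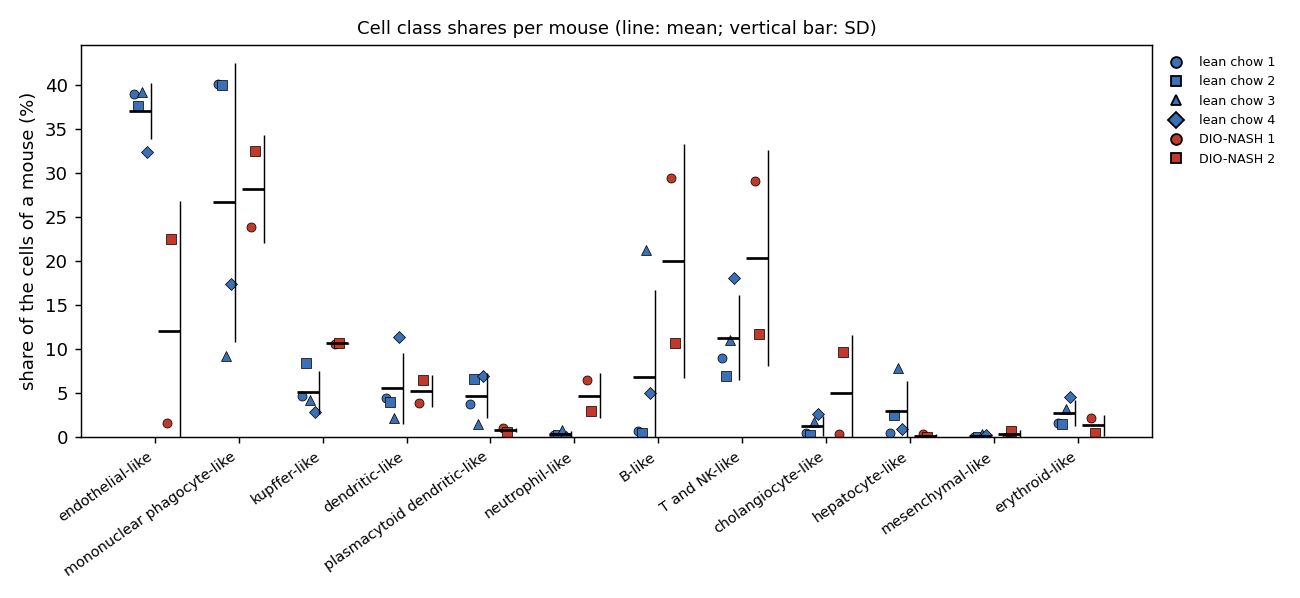
Share of each of the 12 cell classes per mouse, in percent of the cells of that mouse, with 1 point per mouse for the 4 lean and 2 DIO-NASH mice. Neutrophil-like cells lay at 6.51% and 2.91% in the DIO-NASH mice and at or below 0.850% in the lean mice.

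In endothelial-like cells, genes of fatty acid handling were higher in the DIO-NASH mice. Fabp4, a fatty acid-binding protein (chromosome 3, 10204088 to 10208576), rose from 749 ± 226 CPM (SD, n = 4) to 4205 ± 88.2 CPM (SD, n = 2), a log2 fold change of 2.54 (SE 0.31, limma adjusted p = 0.00598). Cd36, a scavenger receptor that takes up fatty acids (chromosome 5, 17781690 to 17888801), rose from 355 ± 75.5 to 1014 ± 149 CPM (log2 fold change 1.53, SE 0.31, adjusted p = 0.0489). Pcdh17, a protocadherin (chromosome 14, 84443563 to 84539002), rose from 118 ± 27.1 to 612 ± 68.2 CPM (2.40, SE 0.37, adjusted p = 0.0144). Tsc22d1, a leucine zipper protein (chromosome 14, 76414961 to 76507765), rose from 86.5 ± 36.8 to 506 ± 238 CPM (2.54, SE 0.48, adjusted p = 0.0437). Cyp26b1, which breaks down retinoic acid (chromosome 6, 84571414 to 84593908), fell from 431 ± 192 to 75.5 ± 8.23 CPM (-2.41, SE 0.41, adjusted p = 0.0262). The other 7 lower genes were mt-Co1, which fell from 65936 ± 10739 to 28018 ± 8008 CPM (-1.25, SE 0.25, adjusted p = 0.0489), and 6 transcripts of hepatocytes. Limma called 12 of 1397 genes, 4 higher and 8 lower, with 201 at an unadjusted p under 0.05, and voom weights on the summed UMIs called 195. The groups did not overlap in 308 genes that were higher and 68 that were lower, 26.9% of the genes against 13.3% by chance on average. All genes share the same libraries and can move together, so this excess is not a test.

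The median gene of this class was 0.19 higher on the log2 scale in the DIO-NASH mice, and relative to it Fabp4 was 2.34, Tsc22d1 2.34, Pcdh17 2.201, Cd36 1.33 and Cyp26b1 -2.60. With CPM over nuclear-encoded UMIs the median gene was at 0.00, Cd36 and Tsc22d1 had adjusted p values of 0.0832 and 0.0792, and the calls were 2 higher and 10 lower in place of 4 and 8. DIO-NASH mouse 1 gave only 31 endothelial-like cells and 31904 UMIs, where 3 UMIs are 94.0 CPM. Lean mice 1 and 2 had 93.1% and 94.9% of this class in cluster 7 (led by Mt2 and Mt1). Cluster 13 (led by Gpihbp1 and Fabp4) held 84.3% and 76.5% of it in lean mice 3 and 4 and 100% and 90.6% in the DIO-NASH mice. Cluster 17 (led by Rspo3 and Vwf) held 14.3% and 16.9% in lean mice 3 and 4 and 0% and 8.64% in the DIO-NASH mice. At clustering resolution 2, cells led by Ehd3, Clec4g and Cyp26b1, with a median of 41.3% mitochondrial UMIs, were 154 and 119 in lean mice 3 and 4 and 9 and 50 in the DIO-NASH mice. The clusters led by Pcdh17 and Kdr and by Fabp4 and Gpihbp1 held 10 and 2 and 23 and 5 cells of lean mice 3 and 4, against 9 and 266 and 13 and 277 cells of the DIO-NASH mice. Another cluster, led by Pcdh17 and Flt4, held 14 and 0 cells of lean mice 3 and 4 and 0 and 45 of the DIO-NASH mice. The class thus held different endothelial-like cells in the groups, and a change within cells was not separated from this. Against lean mice 3 and 4 alone, limma called 67 genes, of which 11 were among the 12, with log2 fold changes of 2.16 for Fabp4, 2.32 for Pcdh17, 2.15 for Tsc22d1 and 1.79 for Cd36. Without DIO-NASH mouse 1 or mouse 2 the adjusted p values were 0.110 and 0.0603 for Fabp4, 0.185 and 0.125 for Pcdh17 and 0.275 and 0.101 for Cyp26b1, which also lost its call without lean mouse 2 (0.0604). Tsc22d1 lost its call without any mouse but lean mouse 4 (adjusted p from 0.0508 to 0.752) and Cd36 without any single mouse (0.0577 to 1.00). At equal depth, with 31 cells per mouse and 300 UMIs per cell, Fabp4 had a log2 fold change of 3.06 (adjusted p = 0.00576). Tsc22d1 had 2.31 (adjusted p = 0.442) and Cd36 0.42 (adjusted p = 0.765), and Pcdh17 was too low to be tested.

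Among the gene lists tested in endothelial-like cells, lipid uptake rose as a set. All 4 measured members were higher, 2 passed over all genes and 2 when adjusted over the list alone (median log2 fold change 1.13, camera adjusted p = 0.000575, adjusted p = 0.164 with an estimated correlation). The 2 that passed over all genes were Fabp4 and Cd36, so the list result is not independent of those 2 calls. The interferon response list rose as well, with all 6 measured members higher and a median log2 fold change of 1.85 (camera adjusted p = 0.00332, adjusted p = 0.351 with an estimated correlation). None of its members passed over all genes and 4 did when adjusted over the list alone. Among them were Iigp1, an interferon-induced GTPase at 36.1 ± 17.3 against 301 ± 232 CPM, Isg15 at 49.7 ± 22.6 against 231 ± 119 CPM and Cxcl9, a T cell-attracting chemokine, at 83.8 ± 32.3 against 223 ± 89.4 CPM. The lean values of Iigp1 rested on 1, 2, 15 and 5 UMIs. The endoplasmic reticulum stress list fell, with 9 of 10 members lower and none past the threshold over all genes or when adjusted over the list alone (median -0.96, camera adjusted p = 0.00192, adjusted p = 0.531 with an estimated correlation). Its call was lost at equal depth (adjusted p = 0.0908), against lean mice 3 and 4 alone (0.120) and with fry (0.484). Its lowest-p members were the chaperones Calr, at 589 ± 296 against 241 ± 55.3 CPM, and Pdia6, at 224 ± 22.5 against 120 ± 48.6 CPM. The immune lists of MHC class I (camera adjusted p = 0.0911), MHC class II (0.136) and inflammatory cytokines (0.138) did not pass. Of these, 2 of the 3 MHC class II members, H2-Aa and H2-Eb1, passed when adjusted over the list alone.

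Lists of endothelial identity did not pass. The capillary list had an adjusted p of 0.104 (0.0173 with nuclear CPM), with 7 of 8 members higher. Ly6a and Plvap were past the threshold when adjusted over the list alone (291 ± 88.5 against 882 ± 354 CPM and 120 ± 44.2 against 312 ± 42.4 CPM). Sinusoidal identity had an adjusted p of 0.520 over 17 members, with a median log2 fold change of 0.19 while the test pointed down. Central zonation had 0.538 with a median of -0.11 and a mean of 0.44, since Fabp4 is one of its 4 members, and portal zonation had 0.556. Adhesion had 0.833, extracellular matrix 0.915 (median -0.13, mean 0.11), glycolysis 0.777, oxidative stress 0.326, immediate early genes 0.326 and haemoglobin 0.242 (0.0467 with nuclear CPM).

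In mononuclear phagocyte-like cells, Kupffer-like cells and monocyte or macrophage-like cells together, genes of lipid-associated macrophages were higher in the DIO-NASH mice as a set. All 15 measured members of that list were higher, with a median log2 fold change of 2.44 (camera adjusted p = 6.94e-08, adjusted p = 0.164 with an estimated correlation). None passed over all genes and 11 did when adjusted over the list alone. Cd63, a tetraspanin of late endosomes (chromosome 10, 128900989 to 128912822), was at 34.1 ± 8.52 CPM (SD, n = 4) against 750 ± 588 CPM (SD, n = 2; log2 fold change 4.19, SE 0.56, limma adjusted p = 0.0588). With nuclear CPM it passed (adjusted p = 0.0453). Trem2, a lipid-sensing receptor, was at 48.1 ± 37.6 against 505 ± 396 CPM, Spp1 (osteopontin) at 13.01 ± 12.6 against 465 ± 548 CPM, and Lpl (lipoprotein lipase) at 113 ± 70.1 against 650 ± 552 CPM. The lean mean of Spp1 lay below 3 UMIs, which were 26.8 to 43.6 CPM there, that of Cd63 within this range and that of Trem2 just above it. The DIO-NASH SD of Spp1 exceeded its mean. Spp1 also led the cholangiocyte-like cluster, which held 7 and 289 cells of DIO-NASH mice 1 and 2. Free RNA of those cells was not tested. The cluster led by Ms4a7, Lpl and Trem2 held 17 and 452 cells of these mice. Apoe, the main apolipoprotein of macrophages (chromosome 7, 19696109 to 19699188), was at 4500 ± 2510 against 33183 ± 20862 CPM (log2 fold change 2.86, SE 0.49, adjusted p = 0.127).

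Antigen presentation and lysosome genes also rose as sets in this class by camera with the preset correlation. All 6 measured MHC class II genes were higher (median log2 fold change 2.19, camera adjusted p = 8.97e-05, adjusted p = 0.497 with an estimated correlation). None passed over all genes and all 6 when adjusted over the list alone, with H2-Ab1 at 1227 ± 1158 against 6319 ± 3765 CPM. The lysosome list had 18 of 20 members higher (median 1.04, adjusted p = 2.04e-05, adjusted p = 0.497 with an estimated correlation). None of them was called over all genes and 9 when adjusted over the list alone, such as the cathepsins Ctsa (113 ± 24.8 against 399 ± 85.9 CPM) and Ctss (1295 ± 590 against 3903 ± 1214 CPM). The MHC class I list had 11 of 11 members higher (median 1.15, adjusted p = 0.00639, adjusted p = 0.497 with an estimated correlation, 0 called over all genes and 1 adjusted over the list alone). The interferon list had 11 of 11 higher (median 1.11, adjusted p = 0.0168, adjusted p = 0.497 with an estimated correlation, 0 over all genes and 2 adjusted over the list alone). The glycolysis list had 8 of 11 higher (median 0.67, adjusted p = 0.0221, adjusted p = 0.497 with an estimated correlation, 0 over all genes and 3 adjusted over the list alone). The immediate early list, genes induced by stress and by tissue dissociation, fell, with 16 of 21 members lower (median -0.48, adjusted p = 0.00192, adjusted p = 0.641 with an estimated correlation) and none called over all genes or adjusted over the list alone. With fry none of these lists passed. The fry adjusted p values were 0.145 for MHC class II, 0.135 for lysosome, 0.143 for MHC class I, 0.135 for interferon, 0.145 for glycolysis and 0.646 for immediate early.

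The complement list did not move one way (camera adjusted p = 0.962), since its members parted. C1qa, C1qb and C1qc, which encode the first component of the classical pathway, were at 625 ± 549, 659 ± 763 and 743 ± 612 CPM in lean against 2538 ± 1225, 3351 ± 1543 and 2622 ± 1258 CPM in DIO-NASH mice. C3 and C4b were at 244 ± 24.99 and 97.9 ± 24.9 CPM against 71.4 ± 41.3 and 17.8 ± 12.5 CPM. These 5 genes passed when adjusted over the list alone and none of them over all genes. Hepatocyte transcripts were lower in this class as well, and a part of free hepatocyte RNA in C3 and C4b was not separated. The Kupffer identity list (adjusted p = 0.394) had a median of 0.26 while the test pointed down. The monocyte list had 0.123 with Ms4a7 alone past the threshold when adjusted over the list alone, and cholesterol efflux had 0.131 (0.0244 with nuclear CPM). Oxidative stress had 0.150, with the ferritin genes Ftl1 and Fth1 and with Prdx1 past the threshold when adjusted over the list alone. Cell cycle had 0.394, endoplasmic reticulum stress 0.538 (median 0.17, test down), inflammatory cytokines 0.661 (median 0.00 and mean 0.24, test down), neutrophil transcripts 0.0911 and haemoglobin 0.133 (0.0169 with nuclear CPM).

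Of 2374 genes tested in phagocytes, limma called 1, Serpina1e, a hepatocyte transcript that was lower, with 310 at an unadjusted p under 0.05 and 35 called with voom weights. The groups did not overlap in 537 genes that were higher and 189 that were lower, 30.6% of the genes against 13.3% by chance on average, which is not a test since genes share libraries. The median gene was 0.25 higher on the log2 scale (-0.06 with nuclear CPM), and relative to it Cd63 was 3.93, Apoe 2.60 and H2-Ab1 2.36. The class lay in different clusters: cluster 0 (led by Thbs1 and Gda) held 88.3%, 78.8%, 1.85% and 76.7% of it in lean mice 1 to 4 and 0.430% and 0.309% in the DIO-NASH mice. Cluster 1 (Plac8, Chil3) held 38.9% in lean mouse 3 and 51.4% and 20.3% in the DIO-NASH mice. The Kupffer-like cluster 3 held 11.7%, 21.2%, 46.3% and 16.4% in the lean and 44.5% and 32.9% in the DIO-NASH mice. Cluster 4, led by Ms4a7, Lpl, Trem2, Apoe and Cd63, held 12.96% in lean mouse 3 and 3.66% and 46.5% in the DIO-NASH mice. Cluster 0 had medians of 440 UMIs and 30.7% mitochondrial UMIs, and cluster 4 of 3215 and 6.89%. The class thus held different cells in the groups, and a change within cells was not separated from this for its genes and lists. Without lean mouse 3 limma called 18 genes. The MHC class I list lost its call against lean mice 3 and 4 alone (adjusted p = 0.374) and with no filter on low counts (0.174). The interferon list lost it without DIO-NASH mouse 1 (adjusted p = 0.332), at equal depth (0.702), with no filter (0.168), with the marker score per cell (0.0845), against lean mice 3 and 4 alone (0.0602) and with voom weights (0.0605). The glycolysis list lost it without lean mouse 3 (0.112) or DIO-NASH mouse 1 (0.0954), at equal depth (0.261), with no filter on low counts (0.739) and against lean mice 1 and 2 alone (0.411). The immediate early list lost it without DIO-NASH mouse 2 (0.0629), at equal depth (0.318) and against lean mice 3 and 4 alone (0.935). Serpina1e lost its call without lean mouse 1 or 2 or DIO-NASH mouse 2 (adjusted p = 0.0602, 0.148 and 0.120).

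In T and NK-like cells, 3 genes were higher in the DIO-NASH mice, of which Ccl5 and Nkg7 are genes of effector and cytotoxic cells. Ccl5, a chemokine of effector and memory T cells (chromosome 11, 83525778 to 83530518), rose from 6331 ± 943 CPM (SD, n = 4) to 21413 ± 6024 CPM (SD, n = 2), a log2 fold change of 1.74 (SE 0.25, limma adjusted p = 0.0300). Nkg7, a protein of cytotoxic granules (chromosome 7, 43437073 to 43438249), rose from 1198 ± 161 to 3651 ± 1466 CPM (1.56, SE 0.27, adjusted p = 0.0300). Ms4a4b, a membrane protein of T cells (chromosome 19, 11443553 to 11467055), rose from 371 ± 153 to 1642 ± 331 CPM (2.22, SE 0.40, adjusted p = 0.0300). The effector and exhaustion list rose, with 7 of 7 members higher, 2 past the threshold over all genes and 3 adjusted over the list alone (median log2 fold change 1.58, camera adjusted p = 0.0221, adjusted p = 0.520 with an estimated correlation). The 2 past the threshold over all genes were Ccl5 and Nkg7, so this list result is not independent of their calls. The MHC class I list rose with 6 of 6 members higher, 0 past the threshold over all genes and 3 adjusted over the list alone (median 0.99, camera adjusted p = 0.0262, adjusted p = 0.497 with an estimated correlation). Its member H2-D1 was at 1410 ± 488 against 3801 ± 865 CPM. Both lists passed with a small margin. MHC class I had an adjusted p of 0.0734 with nuclear CPM, 0.0667 and 0.161 without lean mouse 1 or 2, 0.140 against lean mice 3 and 4 alone, 0.273 at equal depth, 0.704 with no filter on low counts, 0.117 with the first filter and 0.273 with voom weights. The effector list had 0.0523 against lean mice 1 and 2 alone, 0.134 with no filter on low counts and 0.522 with voom weights. With fry the adjusted p was 0.0989 for MHC class I and 0.145 for the effector list.

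Limma called 10 of 540 genes in this class, 3 higher and 7 lower, with 100 at an unadjusted p under 0.05 and 203 called with voom weights. The 7 lower genes were mt-Co1, which fell from 58063 ± 15020 to 14256 ± 7564 CPM (log2 fold change -2.10, SE 0.39, adjusted p = 0.0300), and 6 hepatocyte transcripts. The groups did not overlap in 195 genes that were higher and 27 that were lower, 41.1% of the genes against 13.3% by chance on average. Since genes share libraries and the lower mitochondrial share lifts the other genes together, this excess is not a test. The median gene was 0.47 higher on the log2 scale, and relative to it Ms4a4b was 1.75, Ccl5 1.27 and Nkg7 1.09. With nuclear CPM the median gene was at 0.12, the calls were 0 higher and 5 lower in place of 3 and 7. The adjusted p values were 0.0571 for Ccl5, 0.105 for Ms4a4b and 0.243 for Nkg7. Cluster 16, a T-like cluster led by Ccl5, Nkg7, Cd3g and Ms4a4b, held 55.1% and 68.5% of the class in the DIO-NASH mice and 5%, 6.06%, 9.23% and 3.95% in the lean mice. The T-like cluster 8, led by Il7r, Cd3d and Lef1, held 33.0% and 18.6% against 85.0%, 90.9%, 72.3% and 94.7%. Ms4a4b was among the top 10 genes of cluster 8 too. At clustering resolution 2 the cells led by Il7r, Cd3d and Lef1 were 5, 7, 9 and 3 in the lean mice and 183 and 61 in the DIO-NASH mice. A T-like cluster led by Jchain and Hist1h2ap, with a median of 39.0% mitochondrial UMIs, held 29, 25, 39 and 72 lean cells and 3 and 5 DIO-NASH cells, so Il7r and Lef1 do not describe most lean cells of the class. The comparison is of the whole class, so more cells of the first kind and a change within cells were not separated. The NK-like cluster 12 held 11.8% and 12.9% against 10.0%, 3.03%, 18.5% and 1.32%. Without lean mouse 1 or 4 or DIO-NASH mouse 2 no gene was called (108, 91 and 21 at an unadjusted p under 0.05). The adjusted p values there were 0.0846, 0.0535 and 0.261 for Ccl5, 0.0846, 0.0535 and 0.502 for Nkg7 and 0.0846, 0.0535 and 0.400 for Ms4a4b. Without lean mouse 2 the adjusted p was 0.0783 for both Nkg7 and Ms4a4b, without lean mouse 3 it was 0.0567 for Nkg7, and without DIO-NASH mouse 1 it was 0.0912 for Ms4a4b. The other lists had adjusted p values of 0.133 (endoplasmic reticulum stress), 0.394 (glycolysis), 0.398 (inflammatory cytokines), 0.554 (haemoglobin), 0.668 (immediate early, median 0.62 while the test pointed down) and 0.915 (oxidative stress, median 0.44, test down).

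**Figure D2:**
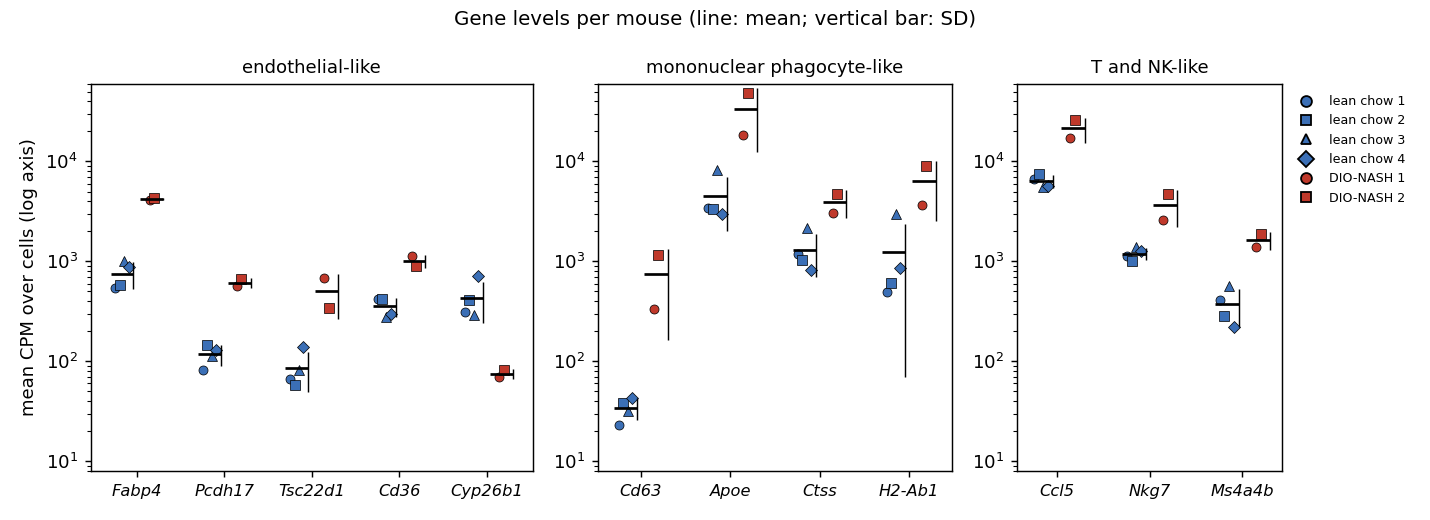
Level of 12 named genes per mouse in CPM on a log axis, in endothelial-like, mononuclear phagocyte-like and T and NK-like cells, with 1 point per mouse. Fabp4 lay at 4142 and 4267 CPM in the DIO-NASH mice and at or below 1004 CPM in the lean mice.

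Transcripts of hepatocytes were lower in all 3 classes. In endothelial-like cells 19 of 20 measured members of the list were lower, 6 passed over all genes and 14 adjusted over the list alone (median log2 fold change -1.84, camera adjusted p = 5.44e-20, adjusted p = 0.0247 with an estimated correlation). In phagocytes 21 of 23 were lower, 1 passed over all genes and 18 adjusted over the list alone (median -1.90, adjusted p = 7.36e-21, adjusted p = 0.0233 with an estimated correlation). In T and NK-like cells 11 of 11 were lower, 6 passed over all genes and 9 adjusted over the list alone (median -2.66, adjusted p = 4.24e-24, adjusted p = 0.0149 with an estimated correlation). These 3 were the only ones of the 18 list results past the threshold, among 47 tests, that also passed with an estimated correlation. The share of T and NK-like cells with an Alb UMI, which counts free albumin RNA, was 62.5%, 39.4%, 46.2% and 50% in the lean mice and 22.1% and 13.8% in the DIO-NASH mice. These were at median depths of 484.5, 490, 1428, 798.5, 1377 and 1039 UMIs.

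Serpina1e, 1 of 5 closely related copies of the alpha-1-antitrypsin gene (chromosome 12, 103946931 to 103958975), was lower in each class. It fell from 388 ± 198 to 1.89 ± 2.67 CPM in endothelial-like cells (log2 fold change -7.34, SE 0.95, limma adjusted p = 0.00598). It fell from 313 ± 118 to 6.33 ± 4.66 CPM in phagocytes (-5.49, SE 0.57, adjusted p = 0.0176), and from 448 ± 262 to 6.41 ± 0.685 CPM in T and NK-like cells (-5.72, SE 0.90, adjusted p = 0.0300). In endothelial-like cells the DIO-NASH mice had 0 and 2 UMIs of it, so the fold rests on the pseudocount and ran from -8.47 to -2.98 over the alternatives. In phagocytes it ran from -6.62 to -2.63 and in T and NK-like cells from -8.74 to -2.98. The copies are similar in sequence, so the values of single copies are uncertain, as are those of Serpina1c and of Mup3 from the Mup family. Serpina3k fell by 3.30 (adjusted p = 0.0144) in endothelial-like and by 4.02 (adjusted p = 0.0300) in T and NK-like cells on the log2 scale. Apoa1, the main protein of high-density lipoprotein, fell by 2.21 (adjusted p = 0.0262) and 2.59 (0.0300), and Apoa2 by 2.15 (0.0393) and 2.66 (0.0300). In endothelial-like cells Mup3 fell by 2.43 (0.0452) and Serpina1c by 2.24 (0.0489), and in T and NK-like cells Hp, which binds free haemoglobin, fell by 2.72 (0.0300) and Alb by 2.55 (0.0378). In endothelial-like cells Serpina1e lost its call without lean mouse 1 or 2 (adjusted p = 0.0853 and 0.0578) and against lean mice 3 and 4 alone (0.121). In phagocytes it lost it without lean mouse 1 or 2 or DIO-NASH mouse 2 (0.0602, 0.148 and 0.120), in T and NK-like cells without any mouse but DIO-NASH mouse 1 (0.0542 to 0.0929). Each of the other hepatocyte transcripts lost its call without DIO-NASH mouse 2 (adjusted p = 0.0808 to 0.317) and, in endothelial-like cells, without DIO-NASH mouse 1 (0.119 to 0.668). Without lean mouse 1 or 4 those of T and NK-like cells lost it too (0.0535 to 0.0861), and without lean mouse 2 Apoa1, Apoa2, Mup3 and Serpina1c lost it in endothelial-like cells (0.0604 to 0.118). There Mup3 also lost it without lean mouse 3 or 4 (0.0517 and 0.0573) and Serpina1c without lean mouse 1 or 4 (0.132 and 0.0577). In T and NK-like cells Hp and Alb lost it without lean mouse 2 (0.0550 and 0.143), Hp, Apoa1 and Apoa2 without lean mouse 3 (0.0733 each), and Alb, Apoa1 and Apoa2 without DIO-NASH mouse 1 (0.0706, 0.0912 and 0.0600).

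Transcripts of the mitochondrial genome were lower in the same 3 classes. In T and NK-like cells 12 of 12 measured members were lower, 1 passed over all genes and 5 adjusted over the list alone (median log2 fold change -0.98, camera adjusted p = 3.67e-15, adjusted p = 0.312 with an estimated correlation). In phagocytes 13 of 13 were lower, 0 passed over all genes and 8 adjusted over the list alone (median -0.92, adjusted p = 3.18e-11, adjusted p = 0.351 with an estimated correlation). In endothelial-like cells 11 of 13 were lower, 1 passed over all genes and 3 adjusted over the list alone (median -0.27, adjusted p = 0.000285, adjusted p = 0.497 with an estimated correlation). The list lost its call without DIO-NASH mouse 2 (adjusted p = 0.139), against lean mice 1 and 2 alone (0.669) and with fry (0.396). With fry it was also lost in phagocytes (0.143) and in T and NK-like cells (0.158). The call of mt-Co1 was lost without lean mouse 1, 2, 3 or 4 or DIO-NASH mouse 2, with adjusted p values of 0.132, 0.110, 0.0517, 0.0580 and 0.323 in endothelial-like cells and 0.0846, 0.0858, 0.0733, 0.0542 and 0.560 in T and NK-like cells. Mitochondrial UMIs made up 24.0%, 22.3%, 38.3% and 43.3% of the UMIs of T and NK-like cells in the lean mice against 16.0% and 10.6% in the DIO-NASH mice.

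**Figure D3:**
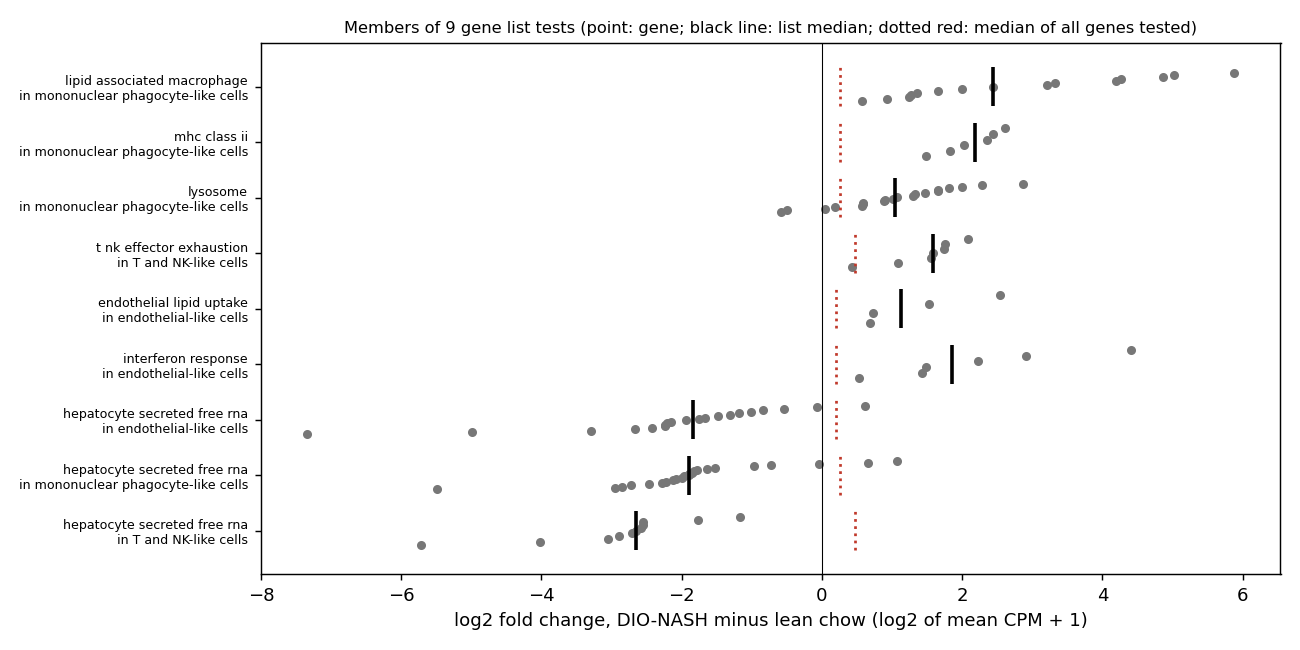
Log2 fold change of each measured member of 9 list tests (points), with the median of the list as a black line and the median of all genes of the class as a dotted red line. All 15 lipid-associated macrophage genes in phagocytes and all 7 effector genes in T and NK-like cells lay above 0, and all 11 hepatocyte transcripts in T and NK-like cells lay below it.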

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

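The tests chosen only after the result was seen were those of depth for T and NK-like cells, of the shallow lean libraries, of hepatocyte RNA of fixed composition, and both tests of Serpina1e.

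Among 142 values compared within the lean group, 9 lay far from the other 3 mice, where chance gives 7.1, and 5 of the 9 were in lean mouse 3. In endothelial-like cells, B2m was at 3794 CPM in lean mouse 3 against 2283 to 2401 CPM in the others. Kit was at 373 CPM in lean mouse 2 against 141 to 159 CPM. In phagocytes, H2-Ab1 was at 2949 CPM in lean mouse 3 against 494 to 860 CPM. Apoe was at 8252 CPM in lean mouse 3 against 2971 to 3435 CPM. Hba-a2 was at 1490.3 CPM in lean mouse 3 against 0 to 236 CPM. Rtp4 was at 44.8 CPM in lean mouse 2 against 97.0 to 107 CPM, and Apoa1 at 431 CPM in lean mouse 1 against 678 to 709 CPM. In T and NK-like cells, mt-Co3 was at 100662 CPM in lean mouse 4 against 67612 to 72002 CPM, and mt-Nd4l at 3465 CPM in lean mouse 3 against 920.3 to 1289 CPM.

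Hepatocyte transcripts were lower in all 3 tested classes of the DIO-NASH mice. Less free hepatocyte RNA of one composition would keep the ratio of each transcript to Alb, and outside hepatocyte-like cells 21.1% of 19 transcripts had ratios that did not overlap between the groups, between the 13.3% that chance gives and the 40% set as evidence against, so this stayed undecided. For Serpina1e the log2 ratio to Alb over the 3 classes changed by -3.62 (lean SD 0.63), which one composition would not give. But Serpina1e was picked for its large fall, and misassigned reads would change the ratio too, so this was left undecided for it. Reads shared between copies also stayed undecided: the other 4 copies changed by 0.0441, against 0.61 had they taken up its reads, with a lean SD of 0.40. A changed transcript mix of the hepatocytes stayed undecided as well, with a rank correlation of 0.268 over few hepatocyte-like cells, and both ratio tests included cholangiocyte-like cells, which hold Alb. In hepatocyte-like cells Serpina1e had 494 UMIs beside 890 of Alb in the lean mice and 1 beside 23 in the DIO-NASH mice. Its log2 ratio to Alb changed there by -3.12, but the DIO-NASH side rests on 6 and 1 cells. A strain variant and an effect of the DIO-NASH state on hepatocytes were not tested and stay open.

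Ccl5, Nkg7 and Ms4a4b were higher in T and NK-like cells of the DIO-NASH mice. Free RNA of these cells was argued against, since B-like cells held 0.612% of the gain. Greater depth was argued against as the whole cause, since all 3 genes passed at equal cells and equal UMIs per cell. A larger NK share was argued against, since the median log2 fold change without the NK-like cluster was 123% of its value with it. A larger share of T cells of the kind led by these genes, and a change within cells, were not tested because the genes lead that cluster. Ms4a4b was also among the top 10 genes of the T-like cluster 8. An effect of the DIO-NASH state stays open as untested.

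Fabp4, Pcdh17, Tsc22d1 and Cd36 were higher in endothelial-like cells of the DIO-NASH mice. More vascular endothelial cells stayed undecided, although the median log2 fold change without the cluster led by Rspo3 and Vwf was 103% of its value with it. That cluster held 0% and 8.64% of the class in the DIO-NASH mice against 0%, 0%, 14.3% and 16.9% in lean mice 1 to 4. Leaving it out could thus hardly lower the change, and vascular endothelial cells in other clusters were not tested. The 2 shallow lean libraries stayed undecided, although all 4 genes passed against lean mice 3 and 4 only. Both DIO-NASH mice lay above every lean mouse in all 4 genes, so leaving out 2 lean mice could hardly undo the change. That fit also called 67 genes in place of 12. At equal cells and UMIs per cell Cd36 was at 0.42 in place of 1.53 (limma adjusted p = 0.765) and Pcdh17 was not testable, so depth stays open for both. There Fabp4 passed at 3.06, while Tsc22d1 was at 2.31 in place of 2.54 with its call lost (0.442). Free RNA was argued against, since T and NK-like cells held a median of 1.03% of the gain over the 4 genes in the higher DIO-NASH mouse. For Tsc22d1 alone it was 7.62% and 7.01% in DIO-NASH mice 1 and 2. A larger share of the cells led by Fabp4 and Pcdh17 stays open, since these genes define those cells, and an effect of the DIO-NASH state stays open as untested.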

How the results depend on the processing

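The tests chosen only after the data were seen were those of the first gene filter, lean mice 3 and 4 or 1 and 2 alone, nuclear CPM, voom weights, pseudocounts of 10 and 50, genes listed in every file and the top 5% of doublet scores. The planned cell filter, first meant as the main setting, also became an alternative only then. Over the alternatives, 2438 values of named genes kept their direction and side of the threshold, 210 passed newly, 177 no longer passed and 0 reversed; for lists these were 1016, 77, 61 and 1, and for shares 161, 8, 17 and 0. Sign changes between values that passed in neither setting count as kept, and there were 16 for genes, 60 for lists and 17 for shares. The hepatocyte list passed under all alternatives in the 3 classes. The list of immediate early genes in T and NK-like cells pointed up against lean mice 3 and 4 alone (adjusted p = 0.00457), and the cause was not tested.

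The counts of called genes, given for endothelial-like cells, phagocytes and T and NK-like cells (12, 1 and 10), depended on the setting, and the cause was not tested. They were 68, 1208 and 1692 with no filter on low counts (16, 1188 and 1678 of them higher), 8, 0 and 0 with a mean of at least 20 UMIs (215, 310 and 124 at an unadjusted p under 0.05), and 4, 0 and 98 with the first filter (2, 0 and 87 higher). They were 3, 0 and 3 at equal depth, 4, 0 and 6 with free RNA genes left out, 67, 0 and 48 against lean mice 3 and 4 alone, 207, 498 and 23 against lean mice 1 and 2 alone, 12, 2 and 5 with nuclear CPM, and 195, 35 and 203 with voom weights (174, 12 and 183 higher). In phagocytes the count was 2 with doublets kept, 5 at resolution 2, 2 at resolution 0.5, 2 with a pseudocount of 10 and 0 with 50, and in T and NK-like cells 0 with the per-cell marker score (109 at an unadjusted p under 0.05). Leaving out 1 mouse gave 3 to 13, 0 to 18 and 0 to 6, where a lone DIO-NASH mouse is assumed to vary like the lean mice. Of the 18 lists past the threshold, 3 passed with an estimated correlation and 6 with fry, and 29 lists passed against lean mice 1 and 2 alone. Of the 12 class shares, 2 passed, against 1 without hepatocytes, 1 with doublets kept, 1 with the per-cell marker score, 3 at resolution 2, 3 with the planned cell filter, 0 against lean mice 3 and 4 alone, 0 by the exact permutation test and 0 to 4 without 1 mouse. The difference in cells per library was 1992, 1871.25 with the planned filter and 1469 to 2515 without 1 mouse, and that in mitochondrial share -19.4, -6.51 and -23.2 to -15.6.

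A replicate block pairs lean mice 1 and 2 with DIO-NASH mice 1 and 2, which share only a number. The pairing check gave correlations of -0.00115, 0.0723 and -0.0269. The block gave 250, 770 and 0 called genes (160 at an unadjusted p under 0.05 in T and NK-like cells), 30 lists and 0 shares, and it rests on 2 pairs.

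Not run were the 2 count-based tools planned (DESeq2 and upper-quartile edgeR) and edgeR on cell numbers. The design set limma for files of normalised values, and voom on the recovered UMIs was run beside it. The stricter cell filter left 6, 5, 1, 0, 309 and 1117 cells, no class had at least 100 cells in enough mice, and the planned cell filter left no class for genes. In endothelial-like cells the per-cell score and the top doublet scores left too few cells. Depth limited DIO-NASH mouse 1 most there, where 3 UMIs are 94.0 CPM.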

Other observations

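No test in this part was planned, and the values below were compared by overlap alone. Kupffer-like cells alone were too few for a test, with 21, 40, 25 and 12 lean and 207 and 320 DIO-NASH cells (11475, 18673, 40460, 12455, 201660 and 464251 UMIs). At clustering resolution 2 the Kupffer-like cluster held 19, 34, 18 and 6 lean and 97 and 122 DIO-NASH cells, and an unnamed cluster led by C1qb, Apoe, Ms4a7, Trem2 and Mmp12 held 2, 6, 7 and 7 lean and 104 and 208 DIO-NASH cells. The values of both paragraphs on Kupffer-like cells therefore do not separate a change within cells from a class that holds different cells in the groups. Of 6 measured MHC class II genes, which present antigen to helper T cells, 5 were higher in both DIO-NASH mice than in every lean mouse, with H2-Ab1 at 2310.2 ± 736 CPM (SD, n = 4) against 6204 ± 1425 CPM (SD, n = 2) and Cd74 at 6655 ± 1558 against 12165 ± 1051 CPM. Of 7 lipid-associated macrophage genes 3 were higher in this way, among them Cd63 at 87.9 ± 46.2 against 816 ± 263 CPM and Lgals3 at 365 ± 146 against 1342 ± 180 CPM. The lean values rested on 1, 1, 2 and 2 UMIs of Cd63 and 6, 4, 11 and 9 of Lgals3. Of 14 lysosome genes 7 were higher and 1, Lamp1, was lower, at 863 ± 144 against 343 ± 77.0 CPM. Chance gives 13.3% in both directions together, and of all 409 genes 25.2% were higher and 9.78% lower.

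Of 12 Kupffer identity genes in these cells, 4 were lower in both DIO-NASH mice than in every lean mouse. Slc40a1, the iron exporter ferroportin, was at 1319 ± 276 CPM (SD, n = 4) against 393 ± 17.4 CPM (SD, n = 2), and Fcna, C6 and Cdh5 were the others. For C6 the separation rests on 1 UMI in lean mouse 4, at 33.8 CPM against 19.7 and 30.5 CPM in the DIO-NASH mice. Clec4f, Vsig4 and Cd5l overlapped between the groups.

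Haemoglobin RNA differed between libraries. A Hbb-bs UMI was present in 2.23%, 3.79%, 52.9% and 47.0% of lean cells and in 95.2% and 32.6% of DIO-NASH cells. In T and NK-like cells, which do not express the gene, the shares were 0%, 0%, 53.8%, 36.8%, 95.6% and 23.2%.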
